A study of Danio rerio with 10 samples.

How the data were processed

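The series measured RNA from whole zebrafish embryos at 28 hpf in 4 libraries of the cebra mutant and 4 libraries of heterozygous siblings. Groups and replicate numbers were taken from the sample titles. The labels' protocol speaks of 5 controls and 5 mutants, while the table analysed here holds 4 libraries of each. The genome sequencing samples, 1 per genotype, were not analysed here. RNA was extracted with a column kit and sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols.

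The authors deposited 1 table of raw read counts per gene model, with 1 column per library and a further column with the length of each model in bases. The counts are whole numbers, not normalized. Alignment files from the Subread package were the input to counting, per the file headers. The submitters' processing notes name cutadapt, DESeq2 and the genome build GRCz11, without versions or roles. The gene annotation, strand setting and treatment of multi-mapping reads are not given in the sources used here, so reads of near-identical copies or of overlapping models could be shared between them. Every column matched the library name of 1 sample. The identifiers (LL followed by digits) matched 0 entries in the symbol tables at hand, and no genome or coordinates were used.

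The design, gene lists, naming rule and other settings to try were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Models were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test, cebra over heterozygotes, two-sided, over all 8 libraries without covariates. Calls are at a Benjamini-Hochberg FDR of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Log2 CPM values used a prior count of 2. Totals of 50634030 to 71877787 counts per library set the precision. Intervals on counts are exact (Clopper-Pearson, 95%) and cover counting error only. No library pair of a group agreed within sampling noise, the chi-square over degrees of freedom being 9.99 or more for every pair, so none was counted as a repeat.

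The gene lists and cell type markers fixed beforehand, the enrichment tests on them and the test of calls by chromosome need gene symbols or positions and could not be run. The naming rule took models past FDR 0.05 with non-overlapping groups and a mean of at least 1 CPM in one group, by smallest p in each direction. The parts of the rule that rest on gene symbols could not be used. It gave 1 higher and 3 lower models. At most 2 per direction are printed by identifier, a limit that was not part of the fixed rule. LL0000031206 was added after its values were seen.

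Whether equal replicate numbers pair the samples was checked before the fits were compared. The deviations from the group means over 25342 models correlated at 0.20, 0.14, 0.15 and 0.27 for numbers 1 to 4. Each library correlated best with the one of its own number in the other group, so the numbers were treated as pairs in the fits with the replicate block. The main fit and the fit without cebra replicate 2 hold no block and leave this pairing out of account. The labels do not say what the numbers share.

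The other settings fixed in this way were RLE, upper-quartile and library-size scaling, no filter and a filter of 1 CPM in all libraries of a group, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust quasi-likelihood, the replicate block, an FDR of 0.01, glmTreat against 1.5-fold, and leaving out each library. Added after seeing the data were library quality weights, offsets from a per-library lowess trend (span 0.3) on log2 model length or on mean level, the fit of pairs 1, 3 and 4 with the replicate block, which leaves out both libraries numbered 2, fits leaving out a further pair, an unblocked fit without both libraries numbered 2, and further DESeq2 fits.

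The fitting code was tested on simulated negative binomial counts with 200 changed models at the observed means, dispersions and library sizes. Each model had the same dispersion in every library, and no pair effects were simulated. The rates are therefore not those of data with an outlying library or with pairs. With all 8 libraries it recovered 4.48% of 1.5-fold, 46.3% of 2-fold and 87.9% of 4-fold changes among 25342 models, with 5 false calls of 97. Without cebra replicate 2 it recovered 49.3%, 70.1% and 97.0% among 25600 models, with 9 false calls of 153. With the 3 pairs and the replicate block it recovered 67.2%, 76.1% and 97.0% among 25447 models, with 25 false calls of 185. That last share is above the nominal 5%.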

Results

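RNA was profiled from whole zebrafish embryos at 28 hours post fertilisation (hpf). Mutants of a line called cebra were set against heterozygous siblings, with 4 RNA libraries in each group. The series title places the work on cilia and the Reissner fiber, an extracellular thread of glycoprotein in the fluid of the brain ventricles and spinal canal. The labels do not say which gene is mutated in cebra, so no targeted gene could be read out to check them. They also do not say whether a library came from 1 embryo or a pool, so the p-values below measure the spread between these libraries. The count table holds 36351 gene models, and totals ran from 50634030 to 71877787 counts per library. Of the gene models, 30786 to 31162 had at least 1 count in a library, and 25342 had enough counts to be tested. The gene models carry LL-type identifiers that the table does not pair with gene symbols or coordinates. No gene name or position can therefore be given, and each model is described by its length and its level in CPM, the read count relative to the TMM-scaled library total. Genomic DNA was also sequenced from 1 cebra and 1 heterozygous sample, which were not analysed here.

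The first question was which gene models differ between cebra embryos and their heterozygous siblings when all 8 libraries are compared. In edgeR's quasi-likelihood test, 5 of 25342 gene models passed a Benjamini-Hochberg FDR of 0.05, of which 4 were lower and 1 was higher in cebra. The most firmly separated was LL0000024109, a model of 1769 bases. It stood at 55.8 ± 6.004 CPM (SD, n = 4) in heterozygotes and at 6.92 ± 2.49 CPM (SD, n = 4) in cebra embryos. It was 8.08-fold lower, with a log2 fold change of -3.01 (SE 0.23) and an edgeR adjusted p of 0.00673. LL0000011872, of 5461 bases, fell from 3.09 ± 0.706 CPM to 0.591 ± 0.140 CPM (SD, n = 4 each), a log2 fold change of -2.37 (SE 0.25) at an edgeR adjusted p of 0.0386. LL0000025514, of 5502 bases, rose from 18.5 ± 1.94 CPM to 40.3 ± 4.90 CPM (SD, n = 4 each), a 2.18-fold increase with a log2 fold change of 1.13 (SE 0.13) and an edgeR adjusted p of 0.0386. The remaining pair of lower models are a model of 3416 bases, at 31.9 CPM in heterozygotes and 3.66-fold lower in cebra, and a model of 2303 bases that was almost absent from cebra libraries. For all 5 models the 4 cebra values lay on one side of the 4 heterozygous values.

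**Figure D1:**
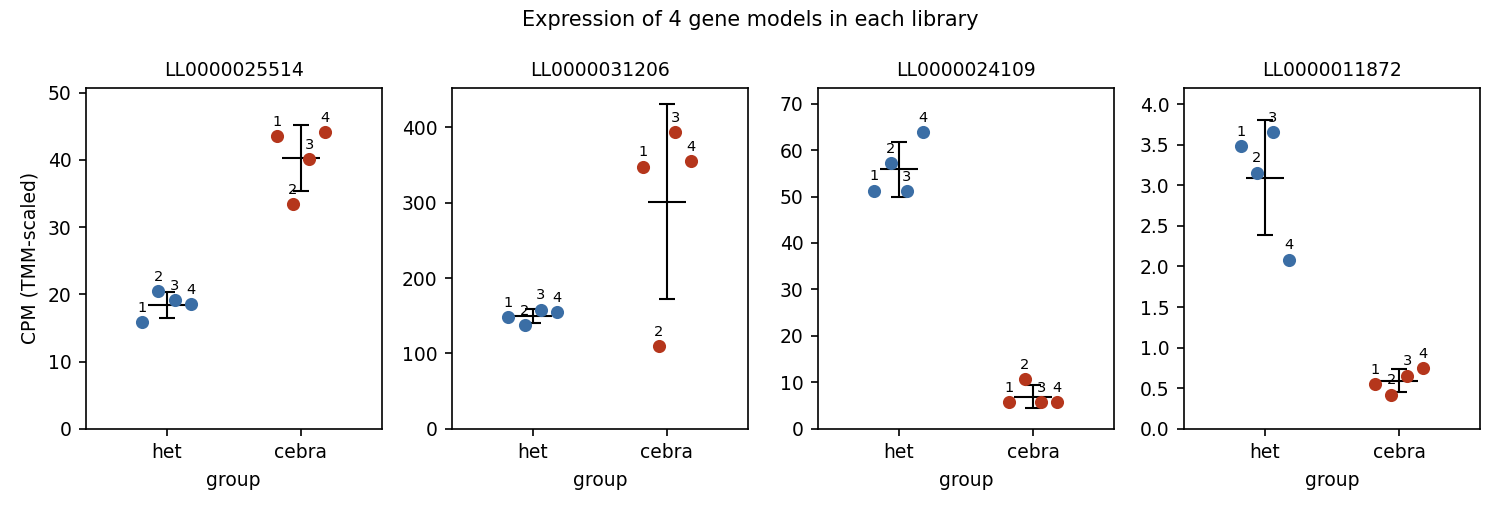
Scaled expression (CPM, linear axes starting at 0) of LL0000025514, LL0000031206, LL0000024109 and LL0000011872 in each het (blue) and cebra (red) library. Points are libraries numbered by replicate, and black bars give the mean ± SD (n = 4). For LL0000031206 the cebra library of replicate 2, at 110 CPM, lies below the het libraries while the others lie at 348 to 393 CPM.

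The count of 5 depended on the library of cebra replicate 2 and on the other libraries. Leaving out cebra replicate 2 gave 25 models. Leaving out cebra replicate 1, 3 or 4 gave 0 in edgeR, with 1093, 1033 and 1174 models at an unadjusted p under 0.05. Without het replicate 1, 2, 3 or 4 the counts were 1, 0, 1 and 2, the 0 standing beside 622 models at an unadjusted p under 0.05. DESeq2, which the submitters' processing notes name, called 51 models over all 8 libraries, 21 higher and 30 lower, including all 5. With the replicate number as a block, edgeR called 0 models over the 4 pairs (1012 at an unadjusted p under 0.05), and DESeq2 called 35, including all 5. Each of these unadjusted counts, and the 964 of the main fit, is below 5% of the models tested, the share that chance gives. They are no sign of further differences, but each of these fits holds cebra replicate 2, so they cannot show that none exist. Without cebra replicate 2 the count was 2847 of 25600 models. With the length-trend offset over all 8 libraries it was 1392 of 25342. Each of these lies above the 5% that chance gives. The log2 fold changes in the blocked edgeR fit were -3.06 for LL0000024109, -2.37 for LL0000011872 and 1.12 for LL0000025514. Their edgeR adjusted p-values in that fit were 0.0942, 0.607 and 0.730.

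A small group of gene models was present in every heterozygous library and had few or no counts in every cebra library. Of all 36351 models, 3 had at least 10 counts in each heterozygous library and at most 3 counts in each cebra library, and none had the opposite pattern. The model of 2303 bases had 48 to 75 counts per heterozygous library (255 in total). In cebra it had 0 counts in replicates 1, 3 and 4 and 2 counts in replicate 2. Its cebra level was 0.835% of the heterozygous level, with an exact 95% interval of 0.101% to 3.05% that covers counting error only. It passed the edgeR test over 8 libraries at an adjusted p of 0.0238. A model of 1488 bases had 87 counts over the heterozygous libraries and 0 over the cebra libraries. The exact 95% interval of its cebra level reached up to 4.61% of the heterozygous level. Its edgeR adjusted p was 0.173 over 8 libraries and 0.0356 without cebra replicate 2. The third, of 495 bases, had 70 counts in heterozygotes and 7 in cebra, which is 10.6% of the heterozygous level (exact 95% interval 4.13% to 23.1%). Its edgeR adjusted p was 0.173 over 8 libraries, 0.0675 without cebra replicate 2 and 0.0139 in the comparison of 3 pairs described below. Among the 35 ways to divide the 8 libraries into 4 and 4, the highest count of such models in any other division was 0. Only 7 of the other divisions part all 4 pairs of equal replicate number, too few for a share under 0.05.

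The cebra library of replicate 2 stood apart from the other 7. Its log2 CPM values had an SD of 0.974 around the median of the other libraries, against 0.274 to 0.386 for the rest. In this library 2429 gene models were more than 2-fold above that median and 3640 were more than 2-fold below, together 23.9% of those tested. In the other libraries the share was 0.998% to 2.896%. Part of the deviation followed gene model length, with a correlation of -0.273 with log2 length. Removing the length trend lowered the SD only to 0.929. The decile of shortest models (median 732 bases) had a median deviation of 0.67 on the log2 scale, and the decile of longest models (median 9117 bases) had -0.72. The first principal component of the 500 most variable models held 75.4% of the variance, with cebra replicate 2 at 63.0 and the other libraries between -11.1 and -6.79. Its total of 64465717 counts was within the range of the others, and its TMM factor of 0.775 lay below their 1.02 to 1.06.

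**Figure D2:**
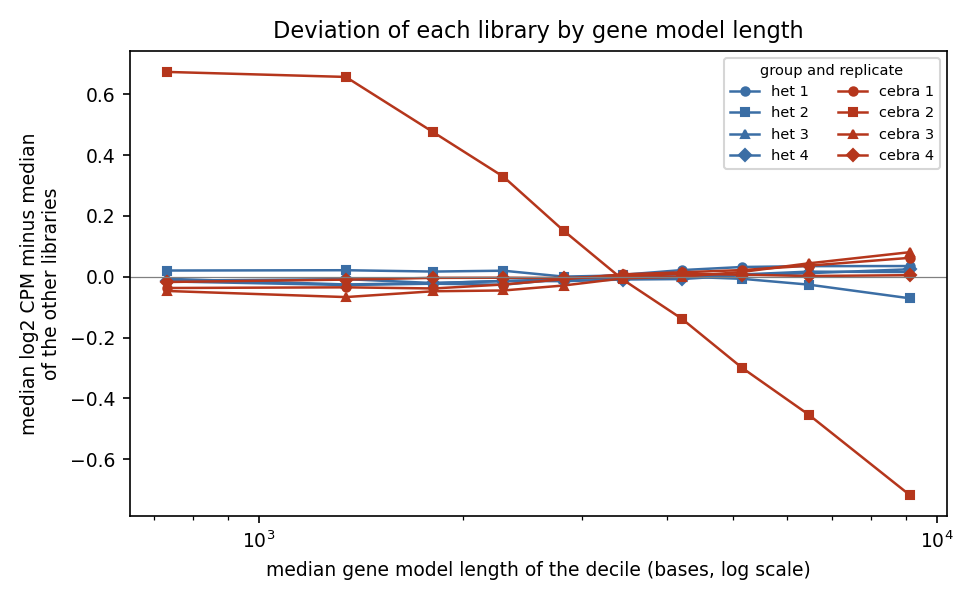
Median deviation of each library (log2 CPM minus the median of the other libraries) by decile of gene model length (x axis, bases, log scale), for het (blue) and cebra (red) libraries with replicates as marker shapes. Cebra replicate 2 runs from 0.67 in the shortest decile to -0.72 in the longest, while the other libraries stay between -0.07 and 0.08.

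Without cebra replicate 2, that is with 3 cebra against 4 heterozygous libraries, 25 gene models passed the edgeR test at FDR 0.05. Of these, 11 were higher and 14 lower in cebra, and all 5 models of the 8-library test were among them. Of the 34 other divisions of these 7 libraries into 3 and 4, 1 called more, with 203 models. LL0000024109 was then 9.81-fold lower (log2 fold change -3.29, SE 0.09, edgeR adjusted p 7.59e-08), and its 3 cebra values were 5.67 to 5.68 CPM. LL0000025514 was 2.31-fold higher (log2 fold change 1.21, SE 0.08, edgeR adjusted p 0.000195). LL0000011872 was 4.72-fold lower at an edgeR adjusted p of 0.0037. An abundant model, LL0000031206 of 12802 bases, was named after its values were seen, as the higher model of smallest p in this fit. It rose 2.45-fold, from 150 ± 8.95 CPM (SD, n = 4) to 366 ± 24.3 CPM (SD, n = 3), with an edgeR adjusted p of 1.11e-05. In cebra replicate 2 it stood at 110 CPM, and over all 8 libraries its edgeR adjusted p was 0.927. Changes of more than 2-fold were seen for 7 of the 11 higher and 9 of the 14 lower models. The strongest of the other higher models, of 5360 bases, went from 1.02 ± 0.329 CPM to 5.29 ± 1.39 CPM (SD, n = 4 and 3), a 5.23-fold increase. At the abundant end, a model of 3334 bases at 221 ± 10.1 CPM in heterozygotes was 1.31-fold lower in cebra, at 168 ± 3.10 CPM (SD, n = 4 and 3). Cebra replicate 2, which took no part in this fit, lay on the same side of the heterozygous mean as the other cebra libraries for 21 of the 25 models. Taking the 25 models of smallest p from each of the 34 other divisions of the 7 libraries into 3 and 4 gave 6 to 23 (median 15), and 6 of those 34 divisions reached 21 or more. The 7 of them that part the pairs 1, 3 and 4, as the real division does, gave 10 to 16, and 8 divisions are too few for a share under 0.05.

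**Figure D3:**
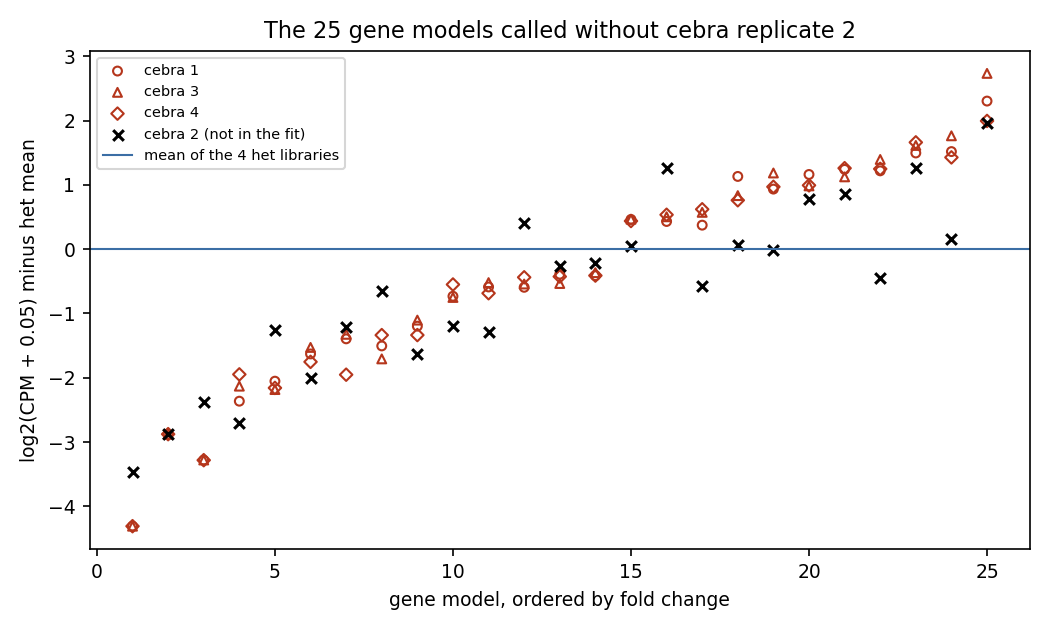
The 25 gene models called without cebra replicate 2, ordered by fold change. The y axis gives log2(CPM + 0.05) minus the mean of the 4 het libraries for cebra replicates 1, 3 and 4 (red) and for replicate 2 (black crosses, not in the fit), which lies on the same side of 0 as the others for 21 of the 25.

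Samples with the same replicate number deviated together in both groups, so the libraries numbered 1, 3 and 4 were also compared as 3 pairs. In this comparison 718 of 25447 gene models passed the edgeR test with the replicate block at FDR 0.05, of which 199 were higher and 519 lower in cebra. Without the block the same 6 libraries gave 11 models, 5 higher and 6 lower. In simulated counts the blocked fit gave 25 false calls of 185, above the nominal 5%. All 25 models of the unpaired 7-library test were among the 718. Most changes were small. The median log2 fold change was 0.42 among the higher models and -0.27 among the lower ones, and 622 of the 718 changed by less than 1.5-fold. More than 2-fold differences were seen for 17 higher and 31 lower models. The lower models were mostly well expressed, with a median of 52.2 CPM in heterozygotes against 7.26 CPM for all models tested. Small changes pass such a test more readily at high counts, so this level cannot be read apart from what the test detects. The higher models had a median of 10.3 CPM, and they were longer (median 4095 bases) than the lower ones (3150 bases) or all tested models (3105 bases). In the decile of longest models, cebra replicates 1 and 3 deviated by 0.062 and 0.081, against 0.035 and 0.015 in het replicates 1 and 3. Number 4 went the other way, with 0.005 in cebra and 0.025 in het. The difference in length therefore cannot be told apart from length trends of the libraries. LL0000024109 had a log2 fold change of -3.28 (SE 0.07, edgeR adjusted p 4.63e-10) in the pairs, and LL0000031206 one of 1.25 (SE 0.05, edgeR adjusted p 4.25e-08). The number of models moved with each pair. It was 645 without pair 1, 96 without pair 3 and 1337 without pair 4. These fits hold few libraries, which leaves little to estimate the variance from. With a trend on expression level removed from each library it was 461, of which 196 were higher and 265 lower, so the share of higher models moved from 27.7% to 42.5%. With a trend on gene length removed it was 914, of which 219 were higher and 695 lower.

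The extent to which the groups were separated was also read without a model. Over all 8 libraries, 553 gene models had every cebra value above every heterozygous value and 584 had every cebra value below. Together these are 4.49% of the tested models, where chance gives 2.86% if all divisions of the libraries are equally likely, which leaves the pairing out of account. The balance of directions turned with the scaling, with 638 above and 491 below under upper-quartile scaling and 442 above and 667 below under library size alone. Without cebra replicate 2 the count was 2939, or 11.5%, where chance gives 5.71% on the same assumption.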

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

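The tests of a wrong label, of abundant models, of length and level trends, of divisions and exchanges of labels and of pair 2 were chosen after the patterns they bear on were seen. In groups of 4 libraries, a library far from its group was looked for in 20 sets of values. The search marked 4, all of them cebra replicate 2, where chance marks about 1 in 20 independent sets. The marks were its TMM factor of 0.775, its SD of 0.974 around the other libraries, its 110 CPM for LL0000031206 and its 10.7 CPM for LL0000024109. They describe the same library and are not independent of each other, so that rate does not weigh them. LL0000031206 was chosen from the fit without that library, so its mark is not independent evidence. The mark for LL0000024109 also rests on how close the other cebra values lie, at 5.67 to 5.68 CPM.

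The first pattern is that cebra replicate 2 stood apart from the other 7 libraries. A heterozygous library under a cebra label is argued against by its 2 counts of the model of 2303 bases, which had 48 to 75 in each heterozygous library, and by its median position of 0.275 over the 25 models called without it, on a scale from the other cebra libraries at 0 to the heterozygous libraries at 1, although over the 718 models of the 3 pairs, most of them changed by less than 1.5-fold, the median position was 0.898. A few models taking most of the counts is argued against too. The 20 most abundant models of cebra replicate 2 held 13.6% of its counts, against 11.6% to 13.0% in the other libraries. Scaled without the most abundant models, 23.9% of the tested models still differed by over 2-fold, against at most 2.899% in the other libraries. The values were TMM-scaled before that step as well, so this share could hardly move and decides little. The gene length trend is present but accounts for little of the spread. With the trend removed the SD went from 0.974 to 0.929, against at most 0.386 elsewhere. A difference in RNA quality or library preparation that acts on more than length remains open, as does a difference of the embryos themselves, and no biological explanation was tested.

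The second pattern is the set of gene models that differ between genotypes in the unpaired fits. Mutants and siblings are separated by genotype at the mutated locus, so models near it also differ in parental haplotype. Without positions, such models could not be told apart from a response to the mutation, here or in the pairs. Over all 8 libraries the real division gave 5 models and was the only one (1) of 35 to reach that number, with a highest other value of 0, but because the numbers pair the libraries the fitting comparison is with the 7 other divisions that part all 4 pairs, which gave at most 0 and are too few for a share under 0.05. The replicate block over the 4 pairs gave 0 calls in edgeR. The 1012 models at an unadjusted p under 0.05 are fewer than the 5% of tested models that chance gives. Without cebra replicate 2 the real division gave 25, but 2 of 35 divisions reached that number, the other one setting the libraries numbered 1 and 3 against those numbered 2 and 4 and giving 203, which points to a structure of the libraries along the replicate numbers. The 7 other divisions that part the pairs 1, 3 and 4 gave at most 0.

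The third pattern is the 718 models that differ within the pairs 1, 3 and 4. Exchanging labels within a pair gave at most 3 models, but with 4 exchanges (the real one, 1 of 4, included) no share under 0.05 can be reached. A trend with gene length as the whole cause is argued against by 914 models with a length offset, and a trend with expression level by 461 models with a level offset, although the lower models then went from 519 to 265. The hypothesis of a genotype difference shared by pair 2 was put to that pair, which took no part in the fit. After removal of the length trend, 58.8% of the 718 models moved the same way there. The central 95% of random sets matched on direction, length and level was 42.5% to 49.4%. The one-sided p against these sets was 0.0001, the smallest 10000 draws can give, and genes are not independent. As measured, with the trend left in, the share was 50.1% against 40.5% to 46.1%. With the trend removed, the share was 72.4% for higher models (random sets 41.2% to 54.8%) and 53.6% for lower models (41.2% to 49.1%). It was 87.5% for the 48 models past 2-fold (37.5% to 64.6%). Each share was above the central 95% of its random sets.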

How the results depend on the processing

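The 5 models kept FDR 0.05 under RLE and upper-quartile scaling, the robust fit, no filter (6 calls) and the length-trend offset (7 calls). Counts of calls moved to 3 with library size alone, 1 with the stricter filter, 1 at FDR 0.01, 2 with glmTreat, 8 with limma-voom and 51 with DESeq2. Leaving out 1 library gave 0 to 25 calls, the highest without cebra replicate 2. With the replicate block over 4 pairs edgeR called 0, the block with the length offset 1, and DESeq2 with the block 35. Alternatives chosen after seeing the data gave 90 with library quality weights (cebra replicate 2 had a weight of 0.0531), 11 without both libraries numbered 2, and 371 with DESeq2 on 7 libraries. Those 371 included 4 of the 5 models. The pairs 1, 3 and 4 with the replicate block gave 718, with a level offset 461, and with a length offset 914. Leaving out pair 1, 3 or 4 gave 645, 96 and 1337. The first component held 62.4% of the variance over all tested models. Of 31 alternatives, LL0000024109 kept its direction in all and passed the threshold in 26, with log2 fold changes of -3.34 to -2.93 and adjusted p-values up to 0.0942. LL0000025514 passed in 18 and LL0000011872 in 19, both with their direction kept in all 31. LL0000031206, also higher in all 31, passed in 10. Each of those 10 left out cebra replicate 2 or gave it the weight of 0.0531. The cause of the other shifts was not tested. In simulated counts, which hold no outlying library and no pair effects, the 8-library fit recovered 4.48% of 1.5-fold changes. Gene list, marker and chromosome tests were not run because the identifiers could not be paired with symbols or positions.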

Other observations

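After cebra replicate 2, the libraries with the largest spread were those numbered 4, in both groups. More than 2-fold deviation from the median of the other libraries was seen for 2.896% of the tested gene models in cebra replicate 4 and 2.62% in het replicate 4, against 0.998% to 1.63% in cebra replicates 1 and 3 and het replicates 1, 2 and 3. The correlation of deviations from the group means was also highest for this pair of numbers, at 0.27.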
